A study of Klebsiella aerogenes with 12 samples.

How the data were processed

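RNA was measured in 12 libraries from surface-grown colonies (macrocolonies) of the bacterium Klebsiella aerogenes, 3 libraries in each of 4 groups. Per the labels' protocols, 2 µL of an overnight culture was spotted on semisolid agar with eosin and methylene blue, RNA was extracted with hot phenol, ribosomal RNA was depleted, and libraries were made with a kit that does not keep the strand of the RNA. Sequencing was paired, with reads of 150 bases. Because strand was not kept, reads could not be told apart by strand where genes on opposite strands overlap.

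The deposited table gave 1 FPKM value (a number of fragments scaled by gene length and by the total assigned in the library) for each of 5021 gene identifiers in each library, with no library pooled. HISAT2 2.1, featureCounts and DESeq2 are named in the submitters' processing notes, without their roles. The genome build and the annotation are not given in the sources used here. No reference genome was used. The DNA content of the samples is not given in the sources used here, and any reads from DNA would be counted in the FPKM values. A DNA share alike in all libraries would make fold changes smaller. A share that differed between libraries could also create them. The table does not pair identifiers with gene names, so genes are given by identifier only. Of the identifiers, 4912 have a plain number, 84 have the letter t before the number and 25 the letter r. The table does not say what the letters mark. Reads of t and r identifiers could be shared with near-identical copies, so values of these are uncertain.

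The FPKM values as the authors deposited them were whole multiples of what 1 read was worth. A search for whole-number gene lengths and library totals turned the values of 5019 identifiers into whole reads in every library, within 0.001 of a read (largest deviation 5.9e-05), which was 100% of the identifiers with a value above 0. The other 2 identifiers were listed at 0 in every library. Whether a unit counted here was a read or a read pair is not given in the sources used here, and "read" is used below. All plain identifiers had a length that was a multiple of 3, so lengths are coding lengths, with a median over all identifiers of 822 bases. Library totals ran from 5131132 to 9205409 assigned reads. At the median length, 1 read was worth between 0.132 and 0.237 FPKM, so counting error was small beside the spread between libraries for most genes. The reads were not used for the tests reported first, which rest on the FPKM values.

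The 5014 identifiers with a mean of at least 1 FPKM over the 12 libraries were tested. Values were taken as log2(FPKM + 1), so fold changes are on that scale, which understates changes of low genes. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 12 libraries, with a moderated variance that followed the mean level, and gave two-sided p-values with Benjamini-Hochberg adjustment within a comparison. A gene was said to have risen or fallen when its adjusted p was under 0.05. The 6 comparisons were the later against the earlier hour on day 3, the same on day 4, the difference between those differences, their average, and day 4 against day 3 at each hour. Tests of single measures per library were exact permutation tests, two-sided, in SciPy 1.17.1 under Python 3.11.15, with Benjamini-Hochberg adjustment within each kind of test. Sets of identifiers were tested with camera from limma at a preset correlation of 0.01 between genes and again with the correlation estimated. The gradient along the identifier numbers was measured for each library as a median regression of log2(FPKM + 1) on 1 cosine period (statsmodels 0.14.6) and is given as the ratio of its peak to its trough. Figures were drawn with matplotlib 3.10.9.

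The groups, comparisons, main test, rule for named genes and most alternatives were set before the data were examined. The rule took the genes with the largest absolute log2 fold change among those with an adjusted p under 0.05, whose 3 libraries of 1 group all lay beyond the 3 of the other and whose higher group had a mean of at least 5 FPKM. Where fewer than 5 genes passed, it took the genes with the smallest p. The rule also asked for a gene symbol, which the table does not give, and since identifiers carry no names at most 2 per direction are given in a comparison. For the same reason the 43 gene lists fixed beforehand, and 8 temperature and stress genes, could not be matched, and no test of a gene list was run. The sets of identifiers used in their place (the t and r identifiers, and the 50 identifiers with the highest mean log2 value) and the measures per library were chosen after the values had been seen.

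The procedure was tested on simulated values for the real genes, with 200 genes changed by 1.5-, 2-, 4- or 8-fold and noise that was independent between genes. For day 3 it recovered 52% of the 1.5-fold and 88% of the 2-fold changes, for day 4 52% and 96%, and for the earlier hour on day 4 against day 3 54% and 92%. For the difference of differences it recovered 30% and 72%, for the average 82% and 96%, and for the later hour on day 4 against day 3 58% and 86%. In the same order of comparisons, 13, 17, 17, 15, 17 and 18 unchanged genes were called too, which was 7.10%, 8.99%, 8.95%, 9.32%, 8.37% and 9.47% of the calls in 1 simulation each, above the 5% that the adjusted threshold allows for. Real libraries shared large deviations across many genes, which this simulation left out.

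Whether replicate numbers pair the libraries was checked by the correlation, across genes, of same-numbered libraries in their deviations from the group means, with a bound of 0.1 for every pair of a comparison. The labels give no other pairing. Same-numbered ZT18 and CT18 libraries correlated at 0.101 to 0.482, so the block is given beside that comparison. ZT18 replicate 2, however, correlated better with CT18 replicate 3 (0.313) than with its own number (0.101), so a pairing is not established. In each of the other 5 pairs of groups 0 of 3 same-number pairs exceeded the bound.

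Alternatives were another pseudocount (0.1), no filter, a filter at 10 FPKM, median-ratio scaling, quantile normalization, no variance trend, only the compared groups, the replicate number as a block, and leaving out each library. Added after the values had been seen were limma-voom on the recovered reads with and without library quality weights, an abundance index as a covariate (mean log2 value of the 50 most abundant identifiers minus the median of the library), the replicate block within only the compared groups, and leaving out libraries of groups not compared.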

Results

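The transcriptome of Klebsiella aerogenes, an enteric bacterium, was measured in macrocolony biofilms to compare gene expression under a temperature cycle with that after release into constant temperature. Colonies were kept for 3 days in a cycle of 12 h at 35 °C and 12 h at 36 °C and sampled on day 3 at 6 h and 18 h of the cycle (zeitgeber times ZT6, at 35 °C, and ZT18, at 36 °C). They were then released into constant 35 °C and sampled on day 4 at the corresponding circadian times, CT6 and CT18. Each group had 3 libraries, labelled as separate samples. Nothing in the labels says that they came from separate cultures, so p-values measure the spread between these samples, which may be technical. Mean totals of assigned reads were 5266888 in ZT6, 6376736 in ZT18, 7206740 in CT6 and 7923864 in CT18, so depth was lowest in ZT6. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom between 3.78 and 149).

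Expression values lay in a narrow range in every library. The median over plain identifiers was between 131 and 185 FPKM, and between 75.1% and 84.4% of them lay within 2-fold of the median of their library. The t identifiers took between 0.116% and 0.171% of the reads and the r identifiers between 0.247% and 1.04%. ZT6 replicate 1 stood apart from the other libraries. Its score on the first principal component, which held 65.2% of the variance, was -47.0, against -9.34 to 11.9 elsewhere, and 13.0% of its reads fell on the 50 most abundant identifiers, against 3.37% to 7.52% elsewhere. Among 85 plain identifiers that exceeded 5 times the median in both other ZT6 libraries, 22 were over 2 times the higher of those values in replicate 1 and 6 were under 0.5 times the lower.

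The 50 most abundant identifiers held the largest share of reads in ZT6. They took 8.96% ± 3.58 (SD, n = 3) of the reads in ZT6, 4.80% ± 1.40 in ZT18, 3.96% ± 0.109 in CT6 and 4.83% ± 0.614 in CT18. All 3 ZT6 libraries lay above all ZT18 libraries and above all CT6 libraries. Both differences gave an exact permutation p of 0.1, the smallest that 3 libraries against 3 allow, and an adjusted value of 0.255 over 28 such tests. Day 4 against day 3 gave a difference of -2.48 percentage points (exact permutation p = 0.0476, adjusted 0.167 over 14 tests), which did not pass.

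**Figure D1:**
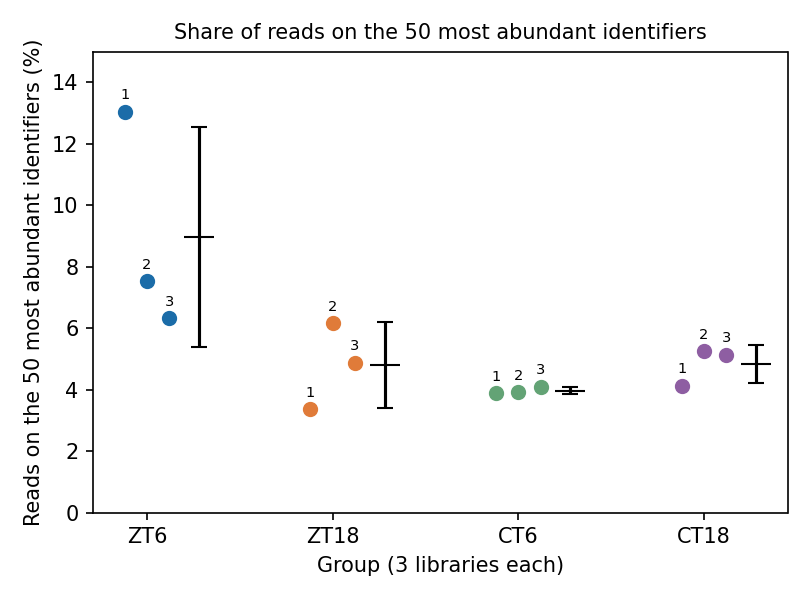
Percent of assigned reads on the 50 most abundant identifiers (vertical axis) in the 12 libraries, by group, with the replicate number above each point and the group mean and SD (n = 3) in black. ZT6 replicate 1 lies at 13.0%, and the CT6 libraries lie between 3.88% and 4.09%.

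On day 3, the first question was what differed between the 6 h and 18 h points of the temperature cycle, which also differed by 1 °C at sampling. The 50 most abundant identifiers had a median log2 fold change from ZT6 to ZT18 of -0.89, with 49 of 50 below 0, while the median over the other 4862 plain identifiers was 0.25. The median over all 5014 genes, also 0.25, was 0.10 without ZT6 replicate 1. Under median-ratio scaling these medians were -1.12 and 0.02, and under quantile normalization, which gives all libraries the same distribution, the abundant identifiers had a median of 0.07. EAE_24120 had 679 ± 123 FPKM in ZT6 and 368 ± 43.8 in ZT18 (SD, n = 3), a log2 fold change of -0.87 (SE 0.16), and EAE_21295 had 515 ± 85.3 and 306 ± 51.4. EAE_07470 was at 118 ± 8.40 and 169 ± 18.7 FPKM, a log2 fold change of 0.51 (SE 0.11), and EAE_09675 at 133 ± 3.04 and 185 ± 12.1.

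None of these identifiers passed the test. With limma, 0 of 5014 genes had an adjusted p under 0.05 (smallest 0.0813), although 2315 had an unadjusted p under 0.05. limma-voom on the recovered reads also called 0 genes. The set of 50 abundant identifiers had an adjusted p of 9.91e-23 with camera at the preset correlation and an adjusted p of 0.151 with an estimated correlation, and 13 members fell and 0 rose when adjusted over the list alone, a list chosen on these samples. The count depended on single libraries and on the weighting, since 2456 genes (1994 higher, 462 lower) were called without ZT6 replicate 3, 1 without ZT6 replicate 2, and 1355 (960 higher, 395 lower) with library quality weights.

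On day 4, at constant 35 °C, the same pair of clock times was compared with no temperature difference at sampling. The median log2 fold change from CT6 to CT18 was 0.28 for the 50 most abundant identifiers (4 of 50 below 0) and -0.01 for the other plain identifiers. Under quantile normalization the abundant identifiers had a median of 0.04. EAE_18335 was at 122 ± 0.817 FPKM in CT6 and 221 ± 30.0 in CT18 (SD, n = 3), a log2 fold change of 0.84 (SE 0.20), and EAE_05545 at 64.5 ± 7.64 and 89.4 ± 9.38. EAE_10375 was at 276 ± 14.3 and 189 ± 24.0 FPKM, a log2 fold change of -0.55 (SE 0.16), and EAE_19540 at 219 ± 9.22 and 174 ± 30.5, with overlapping libraries.

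Again 0 genes passed with limma. The smallest adjusted p was 0.9999, and 63 genes had an unadjusted p under 0.05. In a fit of only CT6 and CT18, 0 genes passed too. There the smallest limma adjusted p was 0.0948 and 452 genes had an unadjusted p under 0.05. The values from the fit of all 12 libraries thus depend on the spread in groups not compared. limma-voom called 0 genes, or 2 with library quality weights, and 1 gene was called without ZT6 replicate 1. The abundant set had an adjusted p of 1.75e-06 at the preset correlation and an adjusted p of 0.422 with an estimated correlation.

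The design asks whether the difference between the hours was the same in the cycle and after release. The fold changes of the 2 days ran against each other: across 5014 genes, Pearson's r between the log2 fold changes on day 3 and on day 4 was -0.486 and Spearman's rho -0.490, and 31.0% of genes had the same sign on both days. Genes are not independent replicates, so these carry no p. Without CT18 replicate 3, r was -0.218. For the 50 most abundant identifiers, the day 4 change exceeded the day 3 change by a median of 1.11 on the log2 scale, with none of the 50 below 0, and for the other plain identifiers the median was -0.26. Median-ratio scaling gave 1.37 and -0.01, and quantile normalization turned the sign for the abundant identifiers (-0.16). EAE_24120 had a difference of differences of 1.21 (SE 0.23) and EAE_07745 of 1.20 (SE 0.22), while EAE_07470 had -0.75 (SE 0.15) and EAE_22385 -0.77 (SE 0.16).

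No gene passed in this comparison. With limma, 0 genes had an adjusted p under 0.05 (smallest 0.144) and 1538 an unadjusted p under 0.05, and limma-voom called 0. Library quality weights gave 1666 genes and leaving out ZT6 replicate 3 gave 3. As a single measure per library, the share of reads on the 50 most abundant identifiers changed by -4.16 percentage points from ZT6 to ZT18 and by 0.871 from CT6 to CT18. The difference of 5.03 had an exact p of 0.005 when hours were relabelled within days, the smallest that 400 relabellings can give, and an adjusted value of 0.035 over 7 measures. This relabelling assumes no difference between hours on either day. Without ZT6 replicate 1 the difference was 2.99 (exact permutation p = 0.025), and without ZT18 replicate 1 it was 4.31 (exact permutation p = 0.095).

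Averaged over both days, the 18 h against 6 h comparison asks which genes differed by clock time on average, and a change on 1 day alone can carry it. EAE_09205 had a mean log2 fold change of 0.40 (SE 0.09), with 52.5 ± 5.37 and 74.4 ± 5.64 FPKM in ZT6 and ZT18 and 71.5 ± 7.26 and 88.9 ± 8.87 in CT6 and CT18 (SD, n = 3). EAE_t24950 had 0.62 (SE 0.16), EAE_r25004 had -0.85 (SE 0.22) and EAE_03265 had -2.19 (SE 0.62). The value of EAE_03265 came almost wholly from day 3, with 9301 ± 12393 FPKM in ZT6 (23482 in replicate 1) and 226 ± 18.2 in ZT18, against 272 ± 73.8 in CT6 and 209 ± 43.4 in CT18. None passed with limma (0 genes, smallest adjusted p 0.474, 287 genes with an unadjusted p under 0.05), and limma-voom gave 0 with or without library quality weights. Without ZT6 replicate 3, 2 genes were called.

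CT6 and ZT6 were sampled at the same temperature and clock time, 1 day apart. The constant temperature was that of the part of the cycle that held ZT6. If release came when the cycle ended, a continued cycle would have given the colonies the same temperatures up to CT6. This comparison would then hold colony age and day of sampling, but no change of temperature by release. It was the only one of the 6 with genes past the threshold in the fit without a replicate block. From ZT6 to CT6, 1812 genes changed, of which 1411 rose (77.9%) and 401 fell. The rises were small and uniform, with a median log2 fold change of 0.45 (quartiles 0.40 and 0.50), and 4 genes rose by more than 2-fold. All of these were t or r identifiers, whose values are uncertain, and plain identifiers reached at most 0.98. The falls were larger, with a median of -0.75 (quartiles -1.04 and -0.57), and 109 genes fell by more than 2-fold. The median over all genes was itself 0.29 and became 0.02 under median-ratio scaling and 0.15 without ZT6 replicate 1. Relative to the median of all genes, the genes that rose had a median change of 0.16 and those that fell -1.04.

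**Figure D2:**
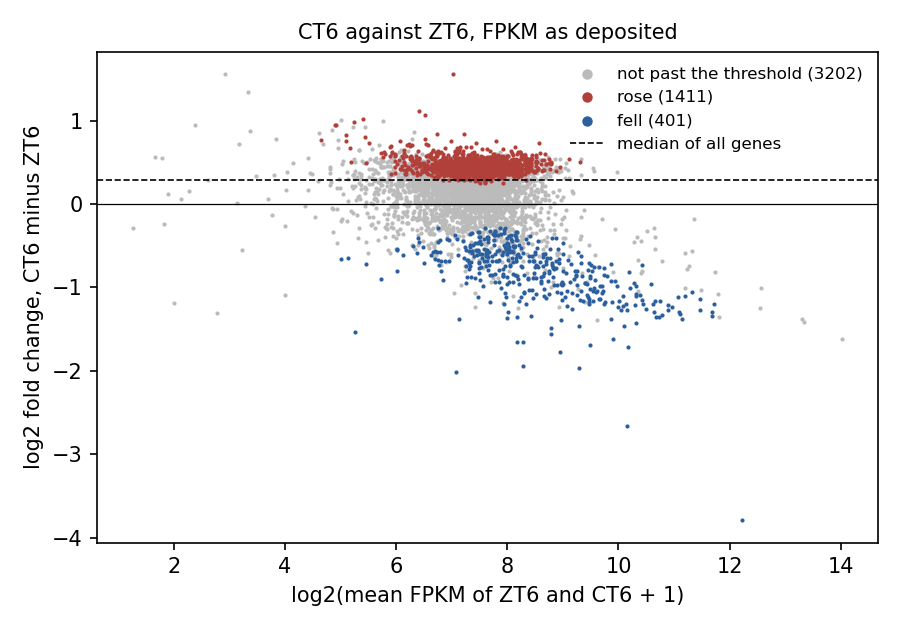
log2 fold change from ZT6 to CT6 (vertical axis) against log2 of the mean FPKM of both groups plus 1 (horizontal axis) for 5014 genes, with the 1411 that rose in red, the 401 that fell in blue and the rest in grey. The dashed line marks the median of all genes (0.29), and the genes that fell reach higher expression levels than those that rose.

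The genes that fell had a median of 386 FPKM in ZT6 and 223 in CT6, and those that rose 149 and 200.5. Of the 50 most abundant identifiers, 26 fell and 0 rose, and all 50 had a log2 fold change below 0 (median -1.11). Adjusted over the list alone, 29 fell, which is no independent evidence since the list was chosen on these samples. The set had an adjusted p of 1.22e-26 at the preset correlation and an adjusted p of 0.110 with an estimated correlation. With median-ratio scaling 11 of them fell and 0 rose, with a median of -1.38 and all 50 below 0, whereas with quantile normalization 0 fell, 2 rose and the median was 0.07. Among 4862 other plain identifiers, 1399 rose and 364 fell. Among 79 t identifiers 10 rose and 11 fell, and among 24 r identifiers 2 rose and 1 fell (with median-ratio scaling 0 and 6, and 1 and 0), and their counts are uncertain where near-identical copies share reads.

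The largest fall was that of EAE_03265, with a coding length of 168 bases, from 9301 ± 12393 FPKM in ZT6 to 272 ± 73.8 in CT6 (SD, n = 3), a log2 fold change of -3.79 (SE 0.88, limma adjusted p = 0.0406). Its ZT6 libraries were at 23482, 3869 and 551 FPKM, so the size of the fall rests largely on replicate 1 (-2.46 without it), while all 3 lay above the CT6 libraries (202 to 349). EAE_07515 fell from 2078 ± 2440 to 184 ± 22.1 FPKM, by 2.66 on the log2 scale (SE 0.65, limma adjusted p = 0.0406). Its ZT6 libraries were at 4860, 1075 and 299 FPKM, and without ZT6 replicate 1 its log2 fold change was -1.62. With median-ratio scaling it was -2.93 and missed the threshold (limma adjusted p = 0.0526). Under the rule for named genes, the largest rises were those of EAE_t24840, with a log2 fold change of 1.56 (SE 0.56, limma adjusted p = 0.0478), and EAE_r24984, with 1.07 (SE 0.23, limma adjusted p = 0.0406). EAE_t24840 went from 45.2 ± 9.63 to 213 ± 250 FPKM, with CT6 replicate 2 at 501 FPKM and the others at 74.1 and 63.6. Without CT6 replicate 2 its log2 fold change was 0.61 (limma adjusted p = 0.110), and its call was also lost with median-ratio scaling, quantile normalization and limma-voom (adjusted p between 1.75e-10 and 0.999 over all alternatives). EAE_r24984 rose from 60.3 ± 21.4 to 122 ± 11.3 FPKM on 22 to 127 reads per library.

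This count was close to the threshold, with a smallest adjusted p of 0.0406 and 2943 genes at an unadjusted p under 0.05, and it moved with the scaling and with single libraries. Median-ratio scaling left 334 genes (60 rose, 274 fell) and quantile normalization 879 (447 rose, 432 fell), so the share of rises went from 77.9% to 17.96% and 50.9%. The count was 840 without ZT6 replicate 1, 3039 without ZT6 replicate 3, 187 without CT18 replicate 3, and 0 without any 1 CT6 library, without ZT18 replicate 2 or 3 and without CT18 replicate 1 or 2. It was 0 in a fit of only the compared groups, with the replicate block and with the abundance index as a covariate. A block within only the compared groups gave 439 genes (118 rose, 321 fell). limma-voom called 1903 genes, and 2651 with library quality weights.

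**Figure D3:**
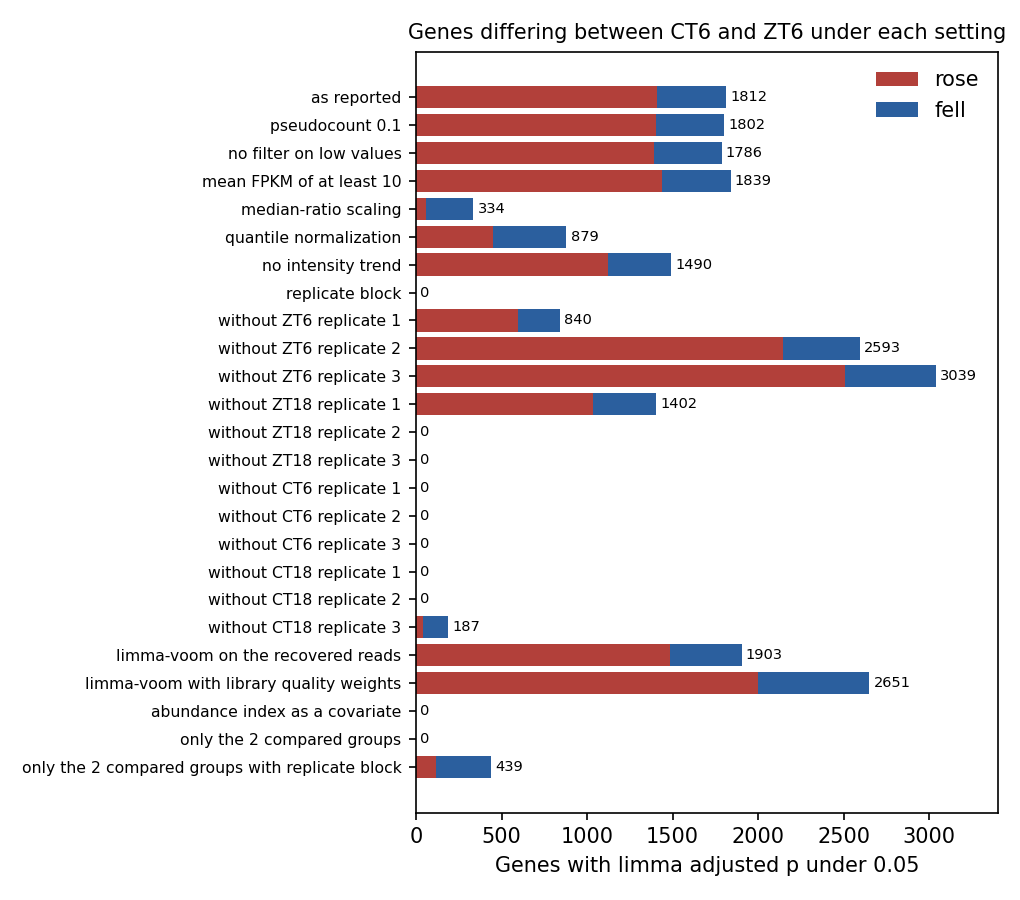
Number of genes with a limma adjusted p under 0.05 between CT6 and ZT6 (horizontal axis) under each setting (vertical axis), split into those that rose (red) and fell (blue). Counts run from 0 to 3039, and 1812 genes were called as reported.

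CT18 and ZT18, also 1 day apart, differed by 1 °C at sampling as well. The 50 most abundant identifiers had a median log2 fold change of 0.06 and the other plain identifiers of 0.01. EAE_18335 was at 99.5 ± 23.9 FPKM in ZT18 and 221 ± 30.0 in CT18 (SD, n = 3), a log2 fold change of 1.16 (SE 0.20), and EAE_10875 at 4.24 ± 0.533 and 21.5 ± 4.69. EAE_04680 had 250 ± 23.2 and 190 ± 8.41 FPKM, a log2 fold change of -0.39 (SE 0.12), and EAE_19705 had 80.8 ± 5.31 and 63.8 ± 7.54. With limma 0 genes passed (smallest adjusted p 0.305), 183 had an unadjusted p under 0.05, and limma-voom called 0. With the replicate number as a block, 1 gene passed: EAE_18335, higher in CT18 (limma adjusted p = 0.0371, between 0.000365 and 0.999998 over the alternatives). The block is given since ZT18 and CT18 libraries of the same number exceeded the bound, but ZT18 replicate 2 correlated better with CT18 replicate 3. A block within these groups alone gave 2 genes. Library quality weights gave 81 genes (76 higher, 5 lower) and leaving out ZT6 replicate 1 gave 4.

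FPKM values followed the identifier numbers in a broad gradient in every library. The ratio of the peak to the trough of the fitted curve was 1.43 ± 0.0434 in ZT6, 1.43 ± 0.0083 in ZT18, 1.38 ± 0.0015 in CT6 and 1.40 ± 0.0225 in CT18 (SD, n = 3), and the peak lay between identifier numbers 6832 and 7132 in the 12 libraries. Day 4 (1.39 ± 0.0172, n = 6) and day 3 (1.43 ± 0.0281, n = 6) differed by -0.0381, with an exact permutation p of 0.0368 and an adjusted value of 0.167 over 14 tests, which did not pass. In the same family, the standard deviation of log2 values within a library was 0.895 ± 0.0147 on day 4 and 1.01 ± 0.113 on day 3 (exact permutation p = 0.0022, adjusted 0.0303). It was lower in all 6 day 4 libraries than in any day 3 library. The share of plain identifiers within 2-fold of the median was 82.5% ± 1.11 on day 4 and 79.6% ± 2.31 on day 3 (exact permutation p = 0.0043, adjusted 0.0303). Mean totals of reads were higher in both day 4 groups than in either day 3 group. Neither measure of spread was tested at equal depth, and no cause of these differences was tested.

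**Figure D4:**
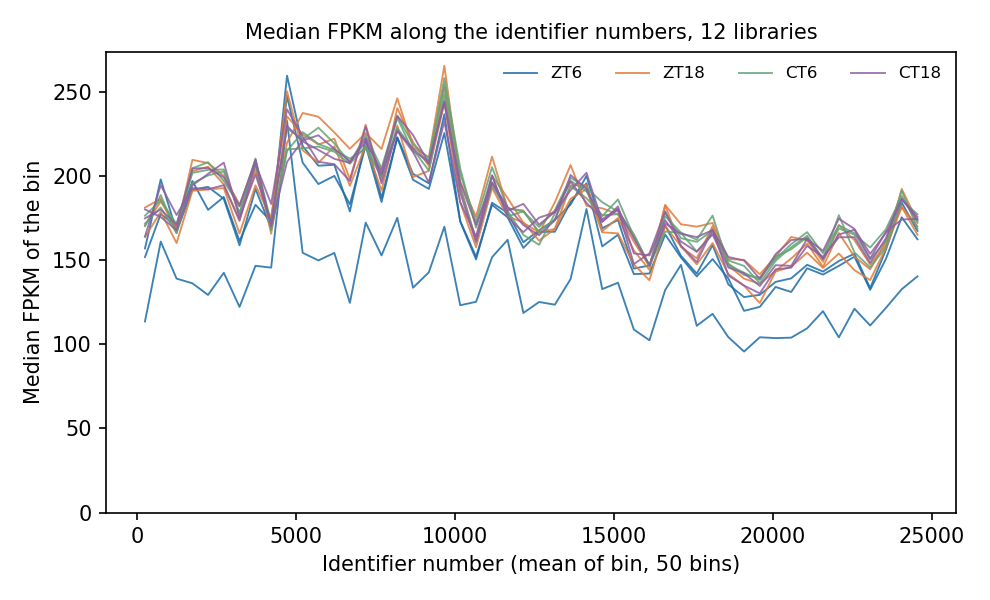
Median FPKM (vertical axis) in 50 bins of plain identifiers ordered by number (horizontal axis), 1 line per library, coloured by group. All 12 lines have a higher median over the lower-numbered bins than over the higher-numbered bins, ZT6 replicate 1 lies below all others in 49 of 50 bins, and profiles of different libraries correlate between 0.671 and 0.987 across bins.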

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

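The measures per library and the tests on them were chosen after the result was seen, and so was reading the count without ZT6 replicate 1 and the rises kept under median-ratio scaling as tests of a cause, although both settings were planned. The change from 6 h to 18 h in the share of reads on the 50 most abundant identifiers differed between day 3 and day 4. It was -4.16 percentage points on day 3 (all 3 ZT18 libraries below all 3 ZT6 libraries) and 0.871 on day 4, a difference of 5.03 (exact p = 0.005 by relabelling hours within days, adjusted 0.035 over 7 measures). It rests in part on single libraries: without ZT6 replicate 1 the difference was 2.99 (exact permutation p = 0.025), and without ZT18 replicate 1 it was 4.31 with an exact permutation p of 0.095. Between days, the share differed by -4.99 percentage points at 6 h (CT6 minus ZT6) and by 0.0326 at 18 h (CT18 minus ZT18). CT6 and ZT6 were sampled at the same temperature, so the difference cannot be credited to the temperature regime. Release, colony age and day of sampling cannot be separated in this design. The abundance index, which describes the same identifiers on the log2 scale, changed by -0.99 and 0.28, a difference of 1.27 (exact p = 0.01 by the same relabelling, adjusted 0.035), and 0.955 to 1.495 with 1 library left out (exact permutation p between 0.005 and 0.03).

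The genes called between CT6 and ZT6 were weighed against technical explanations: ZT6 replicate 1 alone is argued against, since 840 genes were called without it. The median change of all genes, however, went from 0.29 to 0.15 without it. Leaving it out also changed the spread that all comparisons share. For CT18 against CT6, which does not hold it, genes with an unadjusted limma p under 0.05 went from 63 to 361. Library scaling may account for the rises, as 4.25% of them were still called under median-ratio scaling and their median log2 fold change went from 0.45 (median SE 0.14) to 0.18 (median SE 0.08), but that scaling takes the shift of all genes (from 0.29 to 0.02) out of every gene, so a true rise of most genes would look alike. For the falls it stays open, because 44.9% (180 of 401) were still called, between the bounds set beforehand (10% and 50%), and the lost calls are no evidence for scaling: the median log2 fold change went from -0.75 (median SE 0.21) to -1.03 (median SE 0.29), a deepening that this scaling brings to every gene, and 213 of the 221 that lost their call had an unadjusted p after scaling that would have passed before it, since the largest unadjusted p of a called gene went from 0.0181 to 0.00332. Across the 1812 called genes the change correlated at 0.755, and across all genes at 0.562, with the difference between ZT18 replicates 1 and 2, a pair within 1 other group chosen because it differs most in the abundance index, so a share of reads on abundant genes that varies between libraries may account for part of the pattern. With that index as a covariate 0 genes were called, 149 had an unadjusted limma p under 0.05, and EAE_03265 changed by -1.16 rather than -3.79. The index itself differed between ZT6 (mean 4.23) and CT6 (3.01), so this fit cannot tell such a share from a difference between the groups. Colony age, day of sampling and library depth stay open and untested. Totals ran from 5131132 to 5457403 assigned reads in ZT6 and from 6352347 to 8135599 in CT6, so depth did not overlap between the groups. Release could have changed the temperature by CT6 only if it came before the cycle ended, and this was not tested. Of 10 splits of the 6 libraries, too few to weigh chance, the real 1 gave 1812 genes and the highest other 0.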

How the results depend on the processing

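The fits with limma-voom, library quality weights, the abundance index, the block within the compared groups and libraries of groups not compared were added after the result was seen. For genes differing between CT6 and ZT6, reported as 1812, the count was 334 with median-ratio scaling, 879 with quantile normalization and 0 with only the compared groups, with the abundance index as a covariate and with the replicate number as a block. Leaving out 1 library gave 0 to 3039. The counts reported as 0 stayed at 0 under the other planned scalings, filters and pseudocounts. With library quality weights they became 1355 for ZT18 against ZT6, 2 for CT18 against CT6, 81 for CT18 against ZT18 and 1666 for the difference of differences, and stayed at 0 for the average. Leaving out 1 library gave 0 to 2456 for ZT18 against ZT6, 0 to 1 for CT18 against CT6, 0 to 4 for CT18 against ZT18, 0 to 3 for the difference of differences and 0 to 2 for the average, with the highest values reached without ZT6 replicate 3 or, for CT18 against CT6 and CT18 against ZT18, ZT6 replicate 1. The block gave 1 gene for CT18 against ZT18 and changed no other count of 0. Within only the compared groups it gave 2 for CT18 against ZT18, 47 for ZT18 against ZT6, 439 for CT6 against ZT6 and 0 for CT18 against CT6. Of 18 same-number pairs, 3 had deviations that correlated over 0.1, all of them between ZT18 and CT18, so elsewhere the libraries share only a number, and 4 of 12 libraries correlated best with their own number. The correlation of the day 3 and day 4 fold changes stayed below 0, from -0.558 to -0.218 when 1 library was left out, and was -0.346 with the abundance index as a covariate. That fit used 1 slope per gene for both days, and the index changed in opposite directions on them (-0.99 and 0.28). Error in the slope then moves the 2 fold changes apart, so this value cannot show whether their opposition outlasts the index. The correlation could not be computed over called genes only, because neither day had any. The cause of these changes was not tested beyond the tests of scaling. For named identifiers, none of 560 log2 fold changes under alternatives turned its sign. This is no test of direction, since the identifiers were picked on these data. Many settings also leave a fold change as it is by construction, such as blocks, no variance trend and leaving out groups or libraries not compared. Of 96 values for called identifiers 51 missed the threshold, and of 464 for the others 23 passed it. Tests of gene lists were not run, since identifiers could not be matched to gene names. Depth limits low genes most, as 1 read at the median length was worth up to 0.237 FPKM.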

Other observations

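Tests of the narrow range of values were chosen after the result was seen. Genes that fell from ZT6 to CT6 lay beside each other in the numbering. Of 389 plain identifiers that fell, 131 neighbouring pairs both fell, against a median of 30 and at most 52 in 10000 shuffles of the fallen identifiers among those tested. There were 11 runs of at least 4 neighbours that all fell, holding 78 identifiers, and the longest run had 29. The shuffles treated each identifier as independent of its neighbours, and no like count is given for another comparison. Whether the grouping is particular to these falls is therefore open. How the numbers relate to the order of genes on the chromosome was not checked, and no explanation of this grouping was tested.

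The narrow range of FPKM in every library is unusual for messenger RNA. A floor of genomic DNA among the reads, giving genes a like level, may account for it. At most 0.468% of plain identifiers lay below 0.1 times the median in any library, but this restates the narrow range and cannot decide whether there is a floor. Even coverage of all identifiers would be 215 FPKM. Rescaling of single genes by the authors is argued against, because 100% of identifiers with a value above 0 gave whole reads. A factor for a whole library would pass that test, since library totals were fitted to the values. The recovered reads summed to between 99.997% and 99.999% of those totals, which argues against such a factor. Of 16 r identifiers over 1000 bases, 9 had a mean under 10 FPKM (median of the 16, 6.10), while the shorter r identifiers had a higher median. The low values would go against a floor of DNA only if reads shared between copies were counted. Whether such reads were left out of the counting was not tested, so these values cannot decide. The gradient along the identifier numbers was not weighed against such a floor either. A floor alike in all libraries would shrink fold changes. A floor that differed between libraries could create them, with falls of abundant genes and small rises of most others. Whether this contributes to the CT6 against ZT6 calls was not tested. Either floor would mean that FPKM does not measure RNA alone. DNA in the samples was not measured here and no biological explanation was tested, so low variation in RNA levels stays open.

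The gradient along the identifier numbers did not differ between days after adjustment (-0.0381, adjusted 0.167), and its unadjusted difference was weighed all the same. Of 462 splits of the 12 libraries into 6 and 6, 17 gave as large a difference (highest other 0.0543), a share under 0.05 before adjustment. Thinning all libraries to 5131132 reads left -0.0390 (exact permutation p = 0.0325), which argues against library totals. Without the fifth of plain identifiers with the highest mean it was -0.0202 (exact permutation p = 0.160), so the share of reads on abundant genes may contribute, although ZT6 replicate 1, with the highest abundance index (4.87), had the lowest ratio (1.38) and leaving it out gave -0.0485 (exact permutation p = 0.00866, against up to 0.0736 without another library). Day, release and colony age cannot be separated in this design.

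For the comparisons with 0 genes, counts of other splits of the libraries say nothing about chance, because no split can give fewer than 0 genes. As many or more came from 10 of 10 splits for ZT18 against ZT6, CT18 against CT6 and CT18 against ZT18 (highest other 0) and from 100 of 100 drawn relabellings for the difference of differences and for the average (highest other 1).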
